A study of Mus musculus with 7 samples.

How the data were processed

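RNA of sorted cardiac endothelial cells from the border zone of infarcted mouse hearts was sequenced in 7 libraries, 4 of wild-type and 3 of Angpt2-deleted mice. Per the labels' protocols, total RNA was extracted with Trizol and 500 ng went into a Lexogen QuantSeq preparation, which reads the 3′ ends of transcripts. Per the submitters' processing notes, the genome build was mm10 and the tools were Bowtie2 and edgeR; their versions, roles and settings are not given in the sources used here, nor is the annotation or whether counting used strand. The deposited values are on a log2 scale, 1 per gene symbol and library. Raised back (2 to the power of the value, minus 1), the low values of each library were whole multiples of 1 step for 98 to 100% of values (within 0.1 of a whole number). That step, the value of 1 read, ran from 0.93 to 1.28. The deposited values thus behaved as the log2 of read counts, scaled by 1 factor per library, plus 1. The unlogged totals still ran from 11.03 to 14.43 M, so the libraries were not scaled to equal totals. No label or header states how the values were made.

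The files held 23282 rows each, of which 7667 had no read in any library. There were 46 repeated symbols, which were kept as separate rows, and 27 rows had a number in place of a symbol. Depth was estimated as the summed unlogged values divided by the value of 1 read. Such estimates, and every count of genes with a read, cover counting only, since the reads carried no molecular identifiers in the sources used here.

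The design chosen before the data were examined was a test on raw counts with scaling and filtering made for counts, with limma's trend method on log2 values foreseen where the files hold normalised values. As the unit was log2, the limma method was used: limma 3.58.1 in R 4.3.3, lmFit with genotype as the only term and eBayes with a trend, on the deposited scale (pseudocount 1). Genes at an unlogged value of 10 or more in at least 3 libraries were tested (10499 genes), with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 change is Angpt2-deleted minus wild-type on the log2(value + 1) scale, which understates changes of low genes. In 20 simulations with the 10499 genes, the comparison recovered 2.7% of genes changed by 2 log2 units, 19.3% at 4, 29.2% at 6 and 44.9% at 8, with 2.25 false calls on average. The simulated noise was normal, independent between genes and without a lower limit. The real values have missing reads and genes that vary together, so these rates may not hold for them.

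There were 38 gene lists fixed before the data were examined. Lists with at least 5 tested members (35) were tested with limma's camera at a preset inter-gene correlation of 0.01; camera with an estimated correlation and fry were run beside it. Mitochondrial transcripts (0 of 15 in the files), lymphocyte markers (0 of 20 tested) and Schwann cell markers (3 of 8 tested) had too few. Single values were compared with exact two-sided permutation tests over the 35 splits of 7 libraries into 3 and 4, whose smallest possible p is 0.0286. Separation was described by principal components of the tested genes.

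Genes were named by a rule fixed before the data were examined: Angpt2; as no gene passed the threshold, the 5 smallest p per direction among genes with a mean log2 value of at least 7.67 (about 4 on the log2 scale of counts per M), skipping clone and model names; for each list described, members with the smallest p in the list's direction and against it; and Vegfa, Slc2a1, Adm, Vcam1, Icam1, Sele and Selp. Coordinates are GENCODE M21 on mm10, 1-based; 10096 of the tested genes (96.2%) matched it by symbol.

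Alternatives planned beforehand were other scalings, filters and pseudocounts, robust moderation, sample quality weights, a replicate block, leaving out each library and other list tests. The replicate block used replicates 1 to 3 of each genotype, so it left out wild-type replicate 4. Alternatives that need raw counts were not run, and scaling by median of ratios, upper quartile and totals was computed directly. Alternatives chosen after seeing the data were a filter on mean value, totals without Rn45s, the fibroblast marker mean as a covariate, leaving out wild-type replicate 1 together with Angpt2-deleted replicate 3, and exact permutation of list means. No label says whether wild-type mice carried Cre or received tamoxifen, so these cannot be separated from genotype. The labels give 3 to 4 mice without saying whether they were pooled within a library, so p-values measure the spread between libraries.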

Results

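Cells sorted as endothelial from the infarct border zone were profiled in mice lacking Angpt2 and in wild-type mice, all after experimental myocardial infarction. Angpt2 encodes angiopoietin-2, a ligand of the endothelial receptor Tie2. Fibroblast markers were high in every wild-type library and in Angpt2-deleted replicate 3, as given below. Angpt2-deleted mice carried floxed Angpt2 and a tamoxifen-inducible Cre expressed from the ubiquitin C promoter; they received 2 mg tamoxifen at 4 weeks of age, and the male mice underwent surgery at 8 to 10 weeks. Cells were depleted of CD45+ leukocytes and sorted as CD31+ and negative for blood lineage markers. The 4 wild-type and 3 Angpt2-deleted libraries held an estimated 11 to 13.1 M reads each. Rn45s, the ribosomal RNA precursor, took 22.3 to 36.1% of the unlogged values.

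The Angpt2-deleted libraries detected more genes. At an unlogged value of 10 or more there were 10450 ± 326 genes (SD, n = 3) against 8188 ± 487 (SD, n = 4) in wild-type (exact permutation p = 0.0286, two-sided, the smallest possible). Estimated reads without Rn45s were 8.67 ± 0.427 M (SD, n = 3) and 8.65 ± 1.12 M (SD, n = 4; exact permutation p = 1). Genes every cell uses were also without a read in some libraries: Hprt had log2 values of 1.20, 8.65, 0.017 and 9.02 in wild-type replicates 1 to 4, and 9.23, 9.21 and 8.83 in Angpt2-deleted replicates 1 to 3. Of the tested genes, 41.2% lacked a read in at least 1 library, so for such genes values are given per library.

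**Figure D1:**
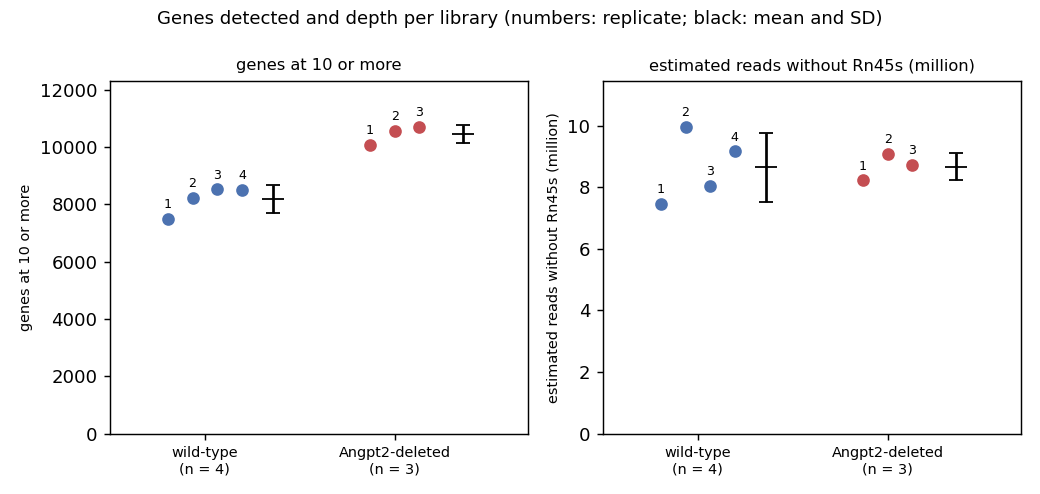
Genes at an unlogged value of 10 or more (left) and estimated reads without Rn45s in M (right), 1 point per library, with the mean and SD of each genotype in black. Genes detected ran from 7485 to 8522 in wild-type and from 10079 to 10695 in Angpt2-deleted libraries, while the estimated reads overlapped.

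Angpt2 itself did not separate the genotypes. Its log2 values were 0.032, 8.02, 9.85 and 5.51 in wild-type replicates 1 to 4 and 4.66, 0.944 and 5.47 in Angpt2-deleted replicates 1 to 3. The log2 change was −2.16 (SE 2.70; limma adjusted p = 0.763), and −4.104 without wild-type replicate 1, −1.442 without wild-type replicate 2, −0.831 without wild-type replicate 3 and −0.79 without Angpt2-deleted replicate 2. Angpt2 lies on chromosome 8 from 18690263 to 18741562 on the minus strand, with its 3′ untranslated region from 18690263 to 18692050, inside Mcph1 (18595131 to 18803189, plus strand). The labels do not say which exons were removed, so 3′ reads may remain after recombination, and reads of Mcph1 cannot be told apart if counting ignored strand. The values do not check the genotype labels.

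No gene passed the threshold between the genotypes. The smallest limma adjusted p was 0.0604; 241 genes were under 0.1 (224 higher and 17 lower in Angpt2-deleted libraries), and 1304 were under an unadjusted 0.05 (792 higher, 512 lower), where 525 would be reached by chance. That count was 733 without Angpt2-deleted replicate 1 and 710 without Angpt2-deleted replicate 2, and under a filter on mean value, chosen after seeing the data, it was 587, mostly lower (188 higher, 399 lower). The median log2 change was 0.638 over all tested genes and 0.0673 over the 4543 with a mean log2 value of at least 7.67. In 826 genes (7.87%) every Angpt2-deleted library lay above every wild-type library and in 357 (3.40%) below, where chance gives 2.86% each way. A gene could enter the test through the 3 Angpt2-deleted libraries alone, which detected more genes. The 7.87% thus includes genes such as Nlrc5, without a read in wild-type, and cannot be told apart from that difference in detection. Leaving out Angpt2-deleted replicate 3 gave 534 genes past the threshold (267 higher, 267 lower), and leaving out Angpt2-deleted replicate 1 gave 73, all higher.

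Among well-expressed genes, those with the smallest p on the higher side were Irf1, a transcription factor of interferon responses, with a log2 change of 2.18 (SE 0.423; limma adjusted p = 0.0604), Cd93, an endothelial surface receptor (3.28, SE 0.681, adjusted p = 0.0606), H2-Q9, a class Ib MHC gene whose reads may be shared with its close relatives (4.66), Cav2, a caveolar protein (4.54), and Atf4, a stress-response transcription factor (1.502). On the lower side were Eln, which encodes elastin (−2.96, SE 0.608, adjusted p = 0.0606), the matrix genes Mgp (−3.32), Prelp (−4.13) and Pcolce (−3.44), and Reep5 (−2.06). In each of these 10 genes all Angpt2-deleted libraries lay on the same side of all wild-type libraries. Choosing genes by smallest p in these same libraries favours such separation, so it is not further evidence. Without Angpt2-deleted replicate 3, all but H2-Q9 and Reep5 passed the threshold, with limma adjusted p from 0.000112 (Mgp) to 0.0327 (Atf4). That comparison set replicates 1 and 2, with fibroblast marker means of 5.20 and 6.33, against wild-type means of 11.94 to 13.30. Pcolce is itself 1 of the 20 fibroblast markers. These passes, and the 534 genes above, cannot be told apart from that difference in markers.

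Markers of cell types parted the libraries, and not by genotype alone. The 20 fibroblast markers averaged a log2 value of 11.94, 12.70, 13.30 and 13.10 in wild-type replicates 1 to 4, and 5.20, 6.33 and 12.25 in Angpt2-deleted replicates 1 to 3. The 19 tested pan-endothelial markers ran the other way, at 7.80, 6.85, 5.99 and 8.19 against 12.26, 12.01 and 8.88. Fibroblast markers were lower relative to other genes (mean log2 change −4.83; camera adjusted p = 4.8e-21; fry, against no change, adjusted p = 0.1), with 19 of 20 past 0.05 when adjusted over the list alone and 0 over all genes. Mfap5 changed by −4.81 and Dcn, which encodes decorin, by −4.13. Pan-endothelial markers were higher relative to other genes (3.84; camera adjusted p = 5.7e-09; fry adjusted p = 0.058), with 14 of 19 past 0.05 adjusted over the list alone and 0 over all genes. Egfl7 changed by 3.22 and Cdh5, which encodes VE-cadherin, by 3.78. With an estimated correlation neither list passed (adjusted p = 0.27 for both). With the fibroblast marker mean as a covariate, chosen after seeing the data, the pan-endothelial mean change was 1.4 (camera adjusted p = 0.63). Pecam1, which encodes the sorting marker CD31, was at 10.72, 7.04, 7.71 and 7.41 in wild-type replicates 1 to 4 and at 12.88, 12.62 and 9.57 in Angpt2-deleted replicates 1 to 3 (limma adjusted p = 0.166).

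Cardiomyocyte markers rose as a list (mean log2 change 2.78; camera adjusted p = 0.039, and adjusted p = 0.27 with an estimated correlation), with 15 of 18 members positive; 2 passed adjusted over the list alone and 0 over all genes. Myh7 was without a read in the 4 wild-type libraries and at 5.12, 5.73 and 6.12 in the Angpt2-deleted libraries, which detected more genes, while Atp2a2 changed by −1.17. That list lost its call without wild-type replicate 3 (adjusted p = 0.12) or Angpt2-deleted replicate 3 (0.11), without wild-type replicate 1 and Angpt2-deleted replicate 3 together (0.089), and with sample quality weights (0.079). Erythroid markers rose (3.37; camera adjusted p = 6.6e-06, and adjusted p = 0.27 with an estimated correlation), with 6 of 9 past 0.05 adjusted over the list alone and 0 over all genes. Its near-identical globin genes share reads, Hbb-b1 changing by 2.28 and Hbb-bs by 2.30. Lymphatic, endocardial, pericyte and smooth muscle, macrophage, neutrophil, platelet and mesothelial markers did not pass, with camera adjusted p of 0.34, 0.15, 0.72, 0.63, 0.72, 0.22 and 0.72, although neutrophil markers passed with fry (0.048).

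**Figure D2:**
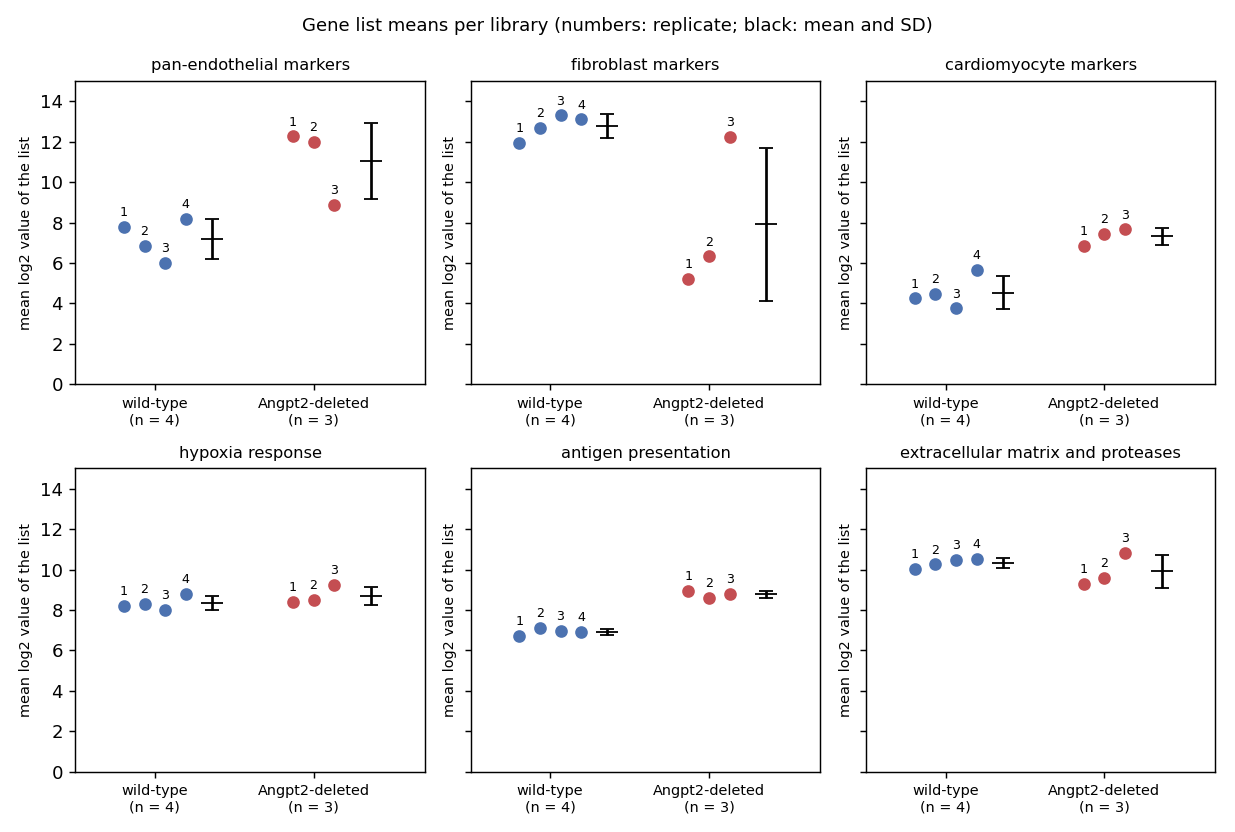
Mean log2 value of 6 gene lists in each library (vertical axis, log2 scale), with the mean and SD of each genotype in black. Angpt2-deleted replicate 3 lay within the wild-type range for fibroblast markers, at 12.25, and with the other Angpt2-deleted libraries for antigen presentation, at 8.80.

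The study's title names hypoxia and inflammation. Hypoxia response genes did not pass camera's test against other genes (32 tested; adjusted p = 0.72, and adjusted p = 0.81 with an estimated correlation). With fry, they passed for change in either direction (adjusted p = 0.017) and not for a shared direction (0.33), and 4 were higher and 6 lower at an unadjusted p under 0.05. Most of the 35 lists passed fry for change in either direction, so that pass is not particular to hypoxia genes. Glycocalyx (0.00022) and venous (0.039) genes passed it too, and glycolysis genes (0.54) did not. The mean log2 change was 0.367 and the median 0.575, while camera's direction, relative to all other genes, was down. The mean change was 0.109 without Angpt2-deleted replicate 3, 0.0703 without that library and wild-type replicate 1 together, and −0.234 (camera up, adjusted p = 0.75) under the mean filter. It was larger, at 0.581 with a pseudocount of 0.1 and 0.521 scaled by totals, with camera's direction still down. One member passed adjusted over the list alone and 0 over all genes. Lox and P4ha1, which act on collagen, changed by −6.17 and −1.63, and Epas1, which encodes HIF-2α, by 2.55, none passing the threshold, although all 3 passed without Angpt2-deleted replicate 3 (0.000311, 0.0229 and 0.00258). In Angpt2-deleted replicates 1 to 3, Lox was at 3.24, 2.50 and 11.02 (wild-type 11.32 to 12.44) and P4ha1 at 9.16, 9.34 and 10.80 (wild-type 10.755 to 11.76). Epas1 was at 13.53, 13.61 and 11.275 (wild-type 9.58 to 10.87). Replicates 1 and 2 were also the libraries low in fibroblast and high in pan-endothelial markers, so these changes cannot be told apart from that difference. Vegfa changed by 4.99 (SE 1.85; limma adjusted p = 0.287) and Adm, which encodes adrenomedullin, by 0.914 (SE 0.616; adjusted p = 0.584), or 1.456 without wild-type replicate 2 and 0.5087 without wild-type replicate 3. Slc2a1, a glucose transporter, was at 8.33, 0, 0.017 and 8.56 in wild-type replicates 1 to 4 and at 7.41, 6.96 and 7.73 in the Angpt2-deleted libraries (limma adjusted p = 0.67). Glycolysis genes did not pass (19 tested; mean change 0.0028, camera down, adjusted p = 0.25), their mean change running from −0.361 without wild-type replicate 3 (0.054) to 0.203 without wild-type replicate 4 (0.34).

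Leukocyte adhesion molecules rose as a list (mean log2 change 2.33; camera adjusted p = 0.016, and adjusted p = 0.27 with an estimated correlation), with 3 of 14 past 0.05 adjusted over the list alone and 0 over all genes. The leading members were Icam2 (4.31), Podxl (3.02) and Pecam1 (3.47), which endothelial cells express at rest, and the pan-endothelial markers were high in the same Angpt2-deleted replicates 1 and 2. Without members that are also cell type markers the list did not pass (adjusted p = 0.092), nor without wild-type replicate 3 (0.052) or with 10 or more required in every library of 1 group (0.053), nor with the fibroblast covariate (0.92, mean change 1.25). The cytokine-induced Vcam1 changed by −0.66 (SE 0.422; limma adjusted p = 0.572; −0.392 without Angpt2-deleted replicate 1 and −1.011 without replicate 3) and Icam1 by 2.27 (SE 1.83; adjusted p = 0.65), or 0.4363 without wild-type replicate 1. Selp, which encodes P-selectin, was at 8.79, 0, 1.11 and 0.005 in wild-type and 4.39, 7.22 and 6.55 in Angpt2-deleted libraries. Sele, which encodes E-selectin, had reads only in Angpt2-deleted replicates 1 and 2 among the 7 libraries, at 9.501 and 8.72, and was not tested. Chemokines and cytokines (camera adjusted p = 0.55) and NF-κB targets (0.35) did not pass. NF-κB targets passed with a replicate block, which also left out wild-type replicate 4 (0.046). The mean change of chemokines was 1.63, and 0.968 without wild-type replicate 3; that of NF-κB targets was 1.48, and 0.901 without wild-type replicate 1.

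**Figure D3:**
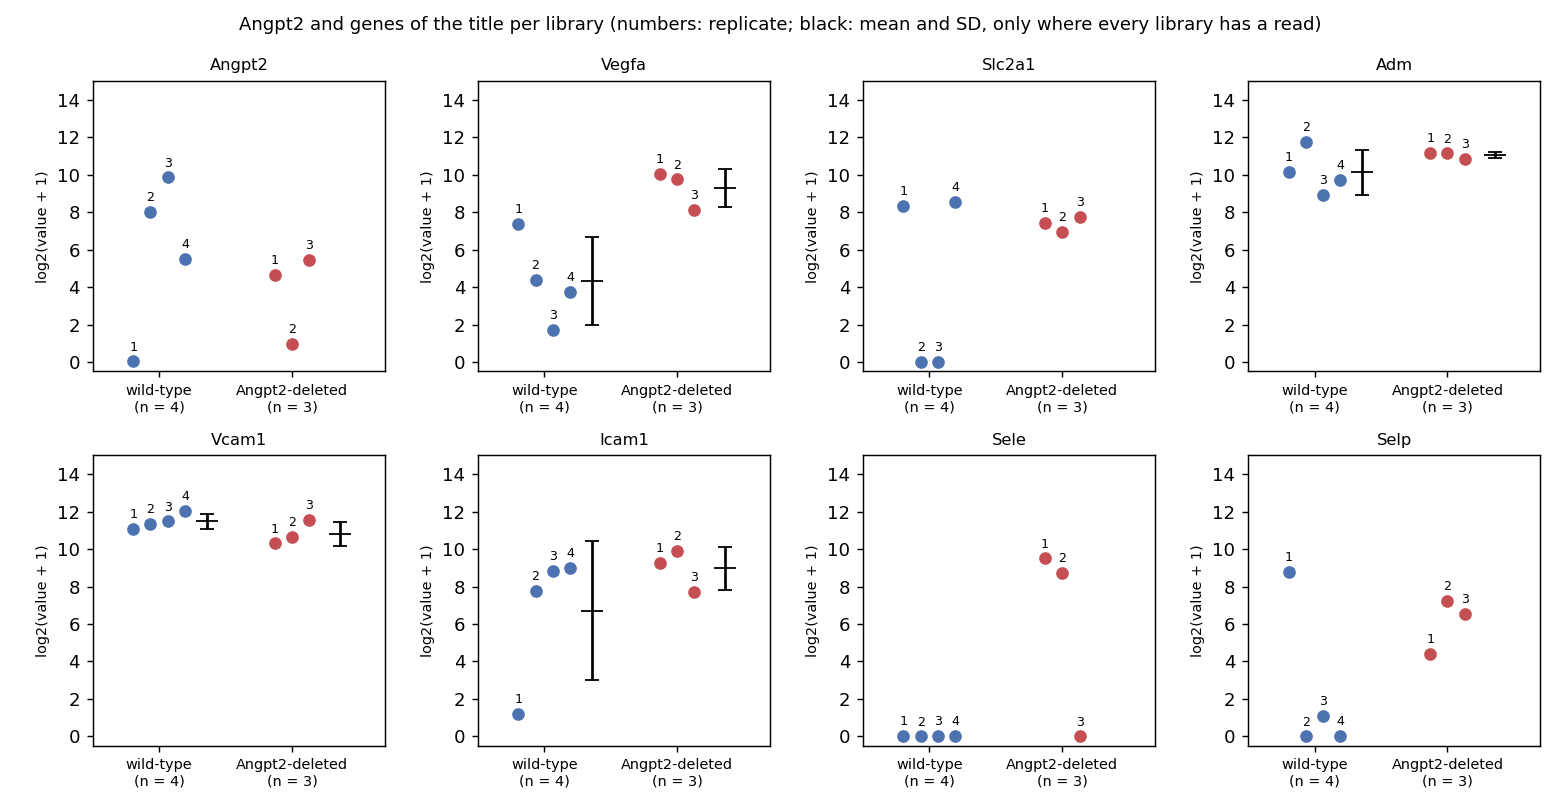
Log2(value + 1) of Angpt2 and of 7 genes tied to hypoxia and leukocyte adhesion, 1 point per library, with the mean and SD of each genotype in black where every library had a read. Vegfa ran from 1.73 to 7.38 in wild-type and from 8.13 to 10.04 in Angpt2-deleted libraries, and the values of the other genes overlapped or were without reads.

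Interferon response genes rose as a list (31 of 36 positive, mean log2 change 1.99; camera adjusted p = 0.01, and adjusted p = 0.28 with an estimated correlation), with 4 past 0.05 adjusted over the list alone and 0 over all genes. Iigp1 and Gbp5, interferon-induced GTPases, changed by 2.21 and 3.75, and Ifi27l2a by −3.79. Antigen presentation genes rose (18 of 20 positive, 1.86; camera adjusted p = 0.018, and adjusted p = 0.27 with an estimated correlation), with 1 past 0.05 adjusted over the list alone and 0 over all genes. Their mean was 8.78 ± 0.173 (SD, n = 3) against 6.92 ± 0.167 (SD, n = 4; exact permutation p = 0.0286, adjusted 0.111 over 35 lists). B2m, the MHC class I light chain, changed by 0.917 and H2-D1 by 0.836, while Nlrc5, a transactivator of MHC class I, was without a read in wild-type and at 8.13, 8.26 and 6.44 in the Angpt2-deleted libraries, which detected more genes. The interferon call was lost without wild-type replicate 3 (adjusted p = 0.052) or Angpt2-deleted replicate 1 (0.069), or with the fibroblast covariate (0.83, mean change 1.34). Under the mean filter the interferon list still passed (camera adjusted p = 0.0049), with a smaller mean change of 0.924. The antigen presentation call was lost without Angpt2-deleted replicate 3 (0.056) or that library and wild-type replicate 1 together (0.07), with 10 or more required in every library of 1 group (0.053), and under the mean filter (0.069, mean change 0.687).

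Endothelial junction genes were higher relative to other genes (24 of 25 positive, mean log2 change 2.26; camera adjusted p = 1.5e-06; fry adjusted p = 0.06), with 9 past 0.05 adjusted over the list alone and 0 over all genes, led by Cav2 and Cdh5. Capillary and fatty acid uptake genes rose (21 of 21 positive, 4.08; camera adjusted p = 6.6e-06), with 6 past 0.05 adjusted over the list alone and 0 over all genes. Cd36, a fatty acid transporter, changed by 6.78 and Fabp4, a fatty acid binding protein, by 4.03. Tip cell genes rose (21 of 27 positive, 2.23; camera adjusted p = 0.039), with 1 past 0.05 adjusted over the list alone and 0 over all genes. Apln, which encodes apelin, changed by 5.66 and Sparc by −1.36. Angpt2-deleted replicates 1 to 3 averaged 11.5, 11.56 and 9.34 for junction genes (wild-type 8.28 to 8.79) and 10.84, 10.42 and 7.53 for capillary genes (4.99 to 6.39), as pan-endothelial markers did at 12.26, 12.01 and 8.88. Of the junction genes, 4 are also pan-endothelial markers. With an estimated correlation none of the 3 lists passed (adjusted p = 0.27, 0.27 and 0.32), nor with the fibroblast covariate, where the mean changes were 0.739 (junctions, 0.92), 1.99 (capillary, 0.56) and 1.23 (tip cell, 0.92, with camera's direction down). The tip cell call was lost without wild-type replicate 3 (adjusted p = 0.054), Angpt2-deleted replicate 1 (0.15) or Angpt2-deleted replicate 2 (0.11), without members that are also cell type markers (0.082), under the mean filter (0.12, mean change 0.924), with 10 or more required in every library of 1 group (0.053), and with a pseudocount of 0.1 (0.05, rounded, and not under the threshold). Arterial and Notch (camera adjusted p = 0.22), venous (0.98), shear stress (0.15), glycocalyx (0.062) and angiopoietin-Tie (0.97) genes did not pass; shear stress genes passed without Angpt2-deleted replicate 3 (0.047) or that library and wild-type replicate 1 together (0.024), and with fry (0.048). Glycocalyx genes passed, as lower than other genes, without Angpt2-deleted replicate 3 (0.03), wild-type replicate 4 (0.049) or both wild-type replicate 1 and Angpt2-deleted replicate 3 (0.031), without a filter (0.037), with a replicate block (0.029) and without cell type markers (0.039).

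Relative to other genes, whose median change was 0.638, extracellular matrix genes were lower (25 of 41 negative, mean log2 change −0.413, median −1.10; camera adjusted p = 4.5e-05), but not against no change (fry adjusted p = 0.7; exact permutation p = 0.343), with 21 past 0.05 adjusted over the list alone in either direction and 0 over all genes. Col8a1 changed by −2.97, Col6a1 by −3.37 and Timp2, a metalloproteinase inhibitor, by −2.35. The mean change was −0.112 without Angpt2-deleted replicate 1, −0.25 without replicate 2 and −0.877 without replicate 3, whose list mean of 10.84 lay above the wild-type 10.04 to 10.54. TGF-β and endothelial-mesenchymal transition genes were also lower relative to other genes (24 of 37 negative, −0.832; camera adjusted p = 0.00024), but not against no change (fry 0.3; exact permutation p = 0.229), with 0 past either adjustment. Serpine1, which encodes the plasminogen activator inhibitor PAI-1, changed by −2.56 and Fn1, which encodes fibronectin, by −2.29, while Eng changed by 1.69. The mean change was −0.488 without Angpt2-deleted replicate 1 and −1.33 without replicate 3. So were complement and coagulation genes (13 of 18 negative, −1.38; camera adjusted p = 6e-05), again not against no change (fry 0.29; exact permutation p = 0.2), with 0 past either adjustment. Cfh changed by −3.44 and C3 by −6.15. C3 was at 4.07 and 4.22 in Angpt2-deleted replicates 1 and 2. In Angpt2-deleted replicate 3, C3 was at 15.18, within the wild-type values of 11.19 to 16.02, and the list mean was 10.4, within 9.44 to 10.48. The mean change was −0.697 without Angpt2-deleted replicate 1 and −2.38 without replicate 3. Angpt2-deleted replicate 3 also stood apart from replicates 1 and 2 for fibroblast markers (12.25 against 5.20 and 6.33), of which the matrix list holds Col5a1 and Mmp2. With an estimated correlation none of these 3 lists passed (adjusted p = 0.27 for each), nor with the fibroblast covariate, where their mean changes turned to 0.653, 0.44 and 0.803 (adjusted p = 0.83, 0.71 and 0.99).

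Cell cycle genes were higher relative to other genes at the margin (26 of 34 positive, mean log2 change 2.03; camera adjusted p = 0.046, fry adjusted p = 0.09, and adjusted p = 0.48 with an estimated correlation), with 2 past 0.05 adjusted over the list alone and 0 over all genes. Ccne2 was at 7.84, 8.31 and 6.87 in the Angpt2-deleted libraries and at most 1.95 in wild-type. The call was lost without wild-type replicate 1 (0.055) or 3 (0.38) or Angpt2-deleted replicate 1 (0.087) or 2 (0.13), under every other scaling (0.056 to 0.075), without a filter (0.092), under the mean filter (0.12) and with a pseudocount of 5 (0.069) and the fibroblast covariate (0.99, mean change 1.05), and held in 9 of 22 settings. Unfolded protein response genes were lower only relative to other genes, and at the margin (16 of 23 negative, median −0.346 but mean 0.154; camera adjusted p = 0.045, and adjusted p = 0.48 with an estimated correlation; fry 0.7; exact permutation p = 0.714), with 2 past 0.05 adjusted over the list alone and 0 over all genes. The chaperone Pdia4 changed by −2.04 and Atf4 by 1.502. That call was lost without wild-type replicate 2 (0.13) or 4 (0.17) or Angpt2-deleted replicate 1 (0.11) or 2 (0.075), under every other scaling (0.056 to 0.11), under the mean filter (0.13), with a pseudocount of 5 (0.059), with a replicate block (0.21) and with the fibroblast covariate (0.65), and held in 9 of 22 settings. Its mean change moved by more than 1.5 times with any library left out, from −0.0762 without wild-type replicate 3 to 0.376 without wild-type replicate 2. Oxidative phosphorylation (camera adjusted p = 0.34), p53 and apoptosis (0.72), immediate early (0.36) and ribosomal protein (0.064) genes did not pass; immediate early genes passed without Angpt2-deleted replicate 3 (0.016), wild-type replicate 4 (0.049) or both wild-type replicate 1 and Angpt2-deleted replicate 3 (0.04), with a replicate block (0.029) and under the mean filter (0.042). Ribosomal protein genes passed, as lower than other genes, without Angpt2-deleted replicate 3 (0.047), wild-type replicate 1 (0.027) or both (0.0096), with sample quality weights (0.008), without a filter (0.026) and with 10 or more required in every library of 1 group (0.039). Their mean log2 change was only −0.0151. They were far from passing under the other scalings (camera adjusted p 0.18 to 0.51) and the mean filter (0.98). Camera's direction was down while the mean was positive for the hypoxia, glycolysis, angiopoietin-Tie, pericyte, oxidative phosphorylation and unfolded protein lists, and while the median was positive for the ribosomal protein and macrophage lists.

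On the first principal component (29.6% of variance) the Angpt2-deleted libraries scored 172, 169 and 51.4 and the wild-type libraries −247, −76.4, −37.0 and −32.0. Over the 4543 well-expressed genes, the correlation across genes, which are not independent replicates, was 0.822 between Angpt2-deleted replicates 1 and 2. Angpt2-deleted replicate 3 correlated with them at 0.437 and 0.483, and with the wild-type libraries at 0.534 to 0.659.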

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

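All tests of explanations in this part were chosen after the results were seen. Among 66 values tested for a library apart from the other 3 wild-type libraries, 5 stood apart, where chance gives about 1 in 20. Wild-type replicate 1 had Icam1 at a log2 value of 1.20 (others 7.79 to 8.98), Selp at 8.79 (others 0 to 1.11), an oxidative phosphorylation mean of 8.47 (others 9.49 to 9.66) and 15.9% of its detected genes between 10 and 100 (others 13.7 to 14%). Wild-type replicate 2 had 1126 genes between 10 and 100 (others 1189 to 1193).

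Fibroblast markers were high in the wild-type libraries and in Angpt2-deleted replicate 3. If genotype set the marker levels, a swap of libraries would put a wild-type library near Angpt2-deleted replicates 1 and 2. The highest endothelial marker mean of a wild-type library was 8.19, far from their 12.01 and 12.26. If fibroblast RNA set the levels instead, a swapped library need not lie near them. The test therefore cannot decide, and a swap and a single wrong label both stay open. RNA from fibroblasts, which the CD31 sort should remove, may be present. The 20 markers held 3.21 to 5.09% of the unlogged total without Rn45s in wild-type. That is under the 5% set for a clear result in 3 of the 4 libraries, and 2 of the 20 are also in another list. The 19 tested pan-endothelial markers held 0.0686 to 0.165%, less than the fibroblast markers in each wild-type library. In Angpt2-deleted replicate 3 they held 0.158%, also less than the fibroblast markers at 3.85%. Replicates 1 and 2 went the other way, with 1.7 and 1.52% endothelial against 0.0719 and 0.0908% fibroblast. By these shares, all wild-type libraries were rich in fibroblast markers, and among the Angpt2-deleted libraries only replicate 3 was. The genotype comparison therefore cannot be told apart from this difference in marker content. Col1a1, an abundant fibroblast transcript, was at 15.60 to 15.98 in wild-type, 10.75 and 11.06 in Angpt2-deleted replicates 1 and 2, and 16.19 in replicate 3. Genotype stays open too, since Angpt2-deleted replicate 3 lay at 12.25, within the wild-type range, and 1 library excludes nothing.

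All Angpt2-deleted libraries held more genes between 10 and 100 (2306 to 2674) than the wild-type libraries (1126 to 1193). Greater depth is argued against by a ratio of estimated reads without Rn45s of 1.002. Cell type makeup is not settled by the 2573 such genes of Angpt2-deleted replicate 3, the only Angpt2-deleted library in the wild-type range for fibroblast markers. Fewer starting molecules in the wild-type libraries may contribute. Genes at 10 or more in a single library had a median unlogged value of 129 to 170 in wild-type and 54 to 63.1 in Angpt2-deleted libraries. That difference follows the same split as genotype (exact permutation p = 0.0286). Wild-type replicates 1 to 4 correlated at 0.534, 0.639, 0.643 and 0.659 with Angpt2-deleted replicate 3, each above its best correlation with another wild-type library (0.431, 0.524, 0.575 and 0.575), as that explanation predicts. The stricter comparison was not met, as 0.534 is below 0.575, and the test rests on 1 Angpt2-deleted library, so this stays open. Genotype and library making cannot be told apart, as both follow the same split (exact permutation p = 0.0286).

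Other splits of the 7 libraries into 3 and 4 bear on whether chance can be excluded. With 0 genes past the threshold, any split gives as many (35 of 35, the highest other 1), so this count says nothing about chance. For genes at an unadjusted p under 0.05, only the real split, 1 of 35, gave as many as 1304 (the highest other 1076). That is the smallest share possible and argues against chance for this count. It does not separate genotype from detection, as genes could enter through the 3 Angpt2-deleted libraries alone, which detected more genes. The count was 733 without Angpt2-deleted replicate 1 and 710 without replicate 2. Under the mean filter it was 587, and no splits were run there. For lists past the threshold (15 in the real split), 3 of 35 splits gave as many, the highest other 16 (wild-type replicate 4 with Angpt2-deleted replicates 1 and 2), so chance is not excluded for the list count.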

How the results depend on the processing

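Among the alternatives below, a filter on mean value, totals without Rn45s, the fibroblast covariate and the joint omission of wild-type replicate 1 and Angpt2-deleted replicate 3 were chosen after seeing the data; that omission and the covariate rest on measured expression and are not independent evidence. The count of 0 genes past the threshold stayed 0 under every other scaling, no filter, the mean filter, robust moderation, the covariate and a pseudocount of 5. It became 348 with 10 or more in every library of 1 group (8536 genes tested), 470 with sample quality weights, 94 with a pseudocount of 0.1, 274 without both doubted libraries and 241 at an adjusted p under 0.1; leaving out single libraries gave 0 to 534. The cause was not tested. Among genes at an unadjusted p under 0.05, 60.7% were higher in Angpt2-deleted libraries, and 32.0% of the 587 under the mean filter. The scalings moved the median log2 change of tested genes from 0.638 to at most 0.795.

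With fry, a test against no change, 9 lists passed, 7 of them among the 15 called (the others were shear stress genes and neutrophil markers, both at 0.048). The 15 list calls became 0 with an estimated correlation and 3 with the fibroblast marker mean as a covariate, and 10 to 17 when single libraries were left out. Under that covariate the tip cell, complement and coagulation, and cell cycle lists reversed relative to other genes (mean log2 changes 1.228, 0.8032 and 1.05, adjusted p = 0.92, 0.99 and 0.99), the extracellular matrix and TGF-β means turned positive (0.653 and 0.44, adjusted p = 0.83 and 0.71), and antigen presentation (0.033), cardiomyocyte (0.033) and erythroid (0.0094) markers passed; the cause was not tested. The Angpt2 change kept its sign and did not pass under the alternatives fixed beforehand (−4.104 to −0.79 with single libraries left out); it was 0.4552 under the covariate, and Angpt2 was not tested under the filters on every library of 1 group or on the mean. The distance between genotypes on the first component was 54.6% of the range, and 57.4 to 75.6% under 3 alternatives.

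Equal replicate numbers did not pair the libraries: correlations of their deviations were 0.028, 0.004 and 0.018. With a replicate block, which also left out wild-type replicate 4, 0 genes and 17 lists passed. Leaving out that library without a block gave 0 genes and 16 lists, so the block's own effect was not isolated. Tests that need raw counts were not run, and camera has no robust form.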

Other observations

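Housekeeping genes varied in whether they were read at all. Tbp, a general transcription factor, was at a log2 value of 6.89, 0, 0.017 and 7.36 in wild-type replicates 1 to 4 and 0.006, 0.944 and 7.35 in Angpt2-deleted replicates 1 to 3. Actb stayed between 14.77 and 15.62 across the 7 libraries.

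Angpt2-deleted replicate 3 lay below every wild-type library for 6 of 20 fibroblast markers and above every wild-type library for 8 of 19 endothelial markers. Its fibroblast markers held 3.85% of the unlogged total without Rn45s, against 0.0719 and 0.0908% in Angpt2-deleted replicates 1 and 2.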
